A study of Mus musculus with 6 samples.

How the data were processed

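Haematopoietic stem cells (HSC) sorted from mouse bone marrow by flow cytometry were profiled on 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 from wildtype and 3 from PU.1 knockdown animals. Per the labels, each array held RNA pooled from 3 animals. Per the labels' protocols, RNA was extracted with a column kit for small samples, amplified in 2 rounds of reverse transcription and T7 in-vitro transcription, labelled with biotin and read in 1 channel. Such amplification starts from little RNA, favours the 3' ends of transcripts and adds noise to weakly expressed ones. How PU.1 was reduced, which surface markers defined the sort, and the age of the animals are not given in the sources used here.

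The deposited value table holds the authors' processed intensity of each probe set on each array, on a linear scale. The software, background correction and scaling behind these intensity values are not given in the sources used here. The array medians were 90.0, 91.5 and 90.2 for wildtype pools 1, 2 and 3, and 81.4, 85.7 and 89.0 for knockdown pools 1, 2 and 3. Between 264 and 409 values per array were below 0, as a background subtraction leaves them. All 44991 probe sets of the table were tested. It held 0 control probe sets with the AFFX prefix, so their signal ratio between the 3' and 5' ends, a check of RNA quality, was not analysed here.

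Values under 1 were set to 1 and log2(value + 16) was taken, so folds of weak probe sets are understated. The medians on that scale ran from 6.605 to 6.748, a spread above the limit of 0.1 set beforehand, and the arrays were therefore quantile normalised. Differences are knockdown minus wildtype on this scale. Each probe set was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The test statistics had 7.81 degrees of freedom in total. For PU.1 and the Jun genes, an exact two-sided permutation test of the 6 log2 values was added, which with 3 arrays against 3 cannot go below 0.1. Pools of separate animals were the replicates, and their number limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

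Probe sets were named from the platform annotation. Of them, 34921 had 1 gene symbol, 930 had several and 9140 had none; those with several or none were tested but not named. Gene IDs of 34717 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. That table was used for names alone and no coordinates are given, since a microarray value has no genome build. For gene lists, each of 18186 genes was represented by its probe set with the highest mean.

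The gene lists were fixed before the data were examined. They covered AP-1, other immediate early genes, the ETS family, myeloid receptors and phagocyte genes, neutrophil granules, stem cell genes, B lymphoid, T and NK, erythroid, megakaryocyte and platelet, mast cell, basophil and eosinophil, MHC class II and dendritic cell, and stromal and endothelial genes. The others were DNA replication, mitosis, p53 targets, interferon response, heat shock, Wnt and Notch, the BCL2 family, ribosomal proteins and the nuclear genes of the respiratory chain. Of the 362 genes in the 20 lists written out by name, 334 were matched to a probe set, and the remaining 28 were not analysed here. The other lists were taken by symbol. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 22 lists. Camera with an estimated correlation and fry were run beside it.

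The rule for named genes, also fixed beforehand, took PU.1, Jun, Junb, Jund and Fos. To these it added the 10 probe sets per direction with the largest differences past the threshold, with 1 symbol, groups that did not overlap and a mean above the median of all probe sets. Places left empty were filled by the smallest p under the same conditions. In each list up to 2 members of smallest p in each direction were taken, by the gene-level probe set. Members past the threshold when adjusted over the list alone, and Vwf, Pf4, Ppbp, Irf8, Ctss, Prg3, Ear3, Alox15 and Thbs4, were named after their values were seen. Separate lists of eosinophil and mast cell genes were also written after the values were seen.

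The tests were first run on simulated data with the probe sets and spreads of the knockdown and wildtype comparison. Probe sets were drawn independently, with the estimated spread of each taken as true, so the simulation lacks the correlation between genes seen in the data. With 44991 probe sets and 100 planted changes of each size, 31% of 2-fold and 79% of 4-fold changes were recovered at the threshold. Beside these, 3 unplanted probe sets were called. With nothing planted, 0 probe sets were called. The alternatives were the values as deposited, centring on medians, pseudocounts of 1 and 64, filters at the 40th and 60th percentile of the mean, eBayes with a trend or a robust prior, array weights, an ordinary linear model, the replicate number as a block, the mean of all probe sets of a gene, the other set tests, and leaving out each array in turn.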

Results

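The series compared gene expression in sorted bone marrow HSC of wildtype mice with that in HSC of PU.1 knockdown mice. PU.1, encoded by Spi1, is an ETS family transcription factor needed for myeloid and B lymphoid development. Each group had 3 arrays, and each array held a pool of 3 animals. The array medians lay between 81.4 and 91.5 intensity units. Pearson correlations across probe sets were 0.964 to 0.979 within the wildtype group, 0.968 to 0.974 within the knockdown group and 0.955 to 0.973 between the groups. The leading principal components held 27.8% and 27.1% of the variance. Values below are log2 intensities as mean ± SD with n = 3 pools per group, and differences carry the standard error (SE) of the limma fit.

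The targeted gene was examined first. Spi1 (probe set 1418747_at) had a mean of 9.88 ± 0.39 in wildtype pools and 8.11 ± 0.92 in knockdown pools. The difference of -1.76 (SE 0.43, 95% interval -2.76 to -0.77) corresponds to 0.295 of the wildtype level on the log2(value + 16) scale. All 3 knockdown pools lay below all 3 wildtype pools, and the deposited intensities averaged 963 ± 215 and 281 ± 140. Knockdown pool 3 was lowest, at a log2 value of 7.06 beside 8.73 and 8.55 in knockdown pools 1 and 2. The exact permutation p was 0.1, the smallest that 3 against 3 allows, and the limma p of 0.00364 did not pass Benjamini-Hochberg adjustment over all probe sets (adjusted p = 0.503).

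The series title names the Jun family of transcription factors, which with Fos proteins form AP-1. Jun was lower in the knockdown pools on both of its probe sets, by a difference of -1.13 (SE 0.23) on 1417409_at, from 11.03 ± 0.28 to 9.91 ± 0.36, and of -0.74 (SE 0.20) on 1448694_at. Junb (1415899_at) averaged 9.63 ± 0.13 in wildtype and 8.94 ± 0.16 in knockdown pools, a difference of -0.69 (SE 0.15). Jund differed by -0.21 (SE 0.17) on the brighter probe set 1449117_at and by 0.037 (SE 0.16) on 1440265_at, and the latter turned to -0.026 with the values as deposited. For both Jun probe sets and for Junb the groups did not overlap, with an exact permutation p of 0.1, the smallest possible, while the exact p of Jund was 0.4 and 0.8. Over all probe sets the limma adjusted p by Benjamini-Hochberg was 0.426 and 0.538 for Jun, 0.473 for Junb, and 0.839 and 0.975 for Jund.

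Of the 11 AP-1 genes measured, 6 had lower and 5 had higher means in the knockdown pools. Jun, Junb, Fos and Fosb had a limma p past the threshold when adjusted over the list alone (Benjamini-Hochberg adjusted p = 0.00935 for Jun, Junb and Fosb and 0.0309 for Fos), and 0 of the 11 did over all probe sets. Fos (1423100_at) differed by -0.46 (SE 0.14) and Fosb by -1.40 (SE 0.32). Batf, a Jun partner expressed in lymphoid and myeloid cells, had a difference of 0.52 (SE 0.19), and Atf3 of 0.095 (SE 0.14). The list as a whole had a mean difference of -0.34, with a camera adjusted p of 0.0103 in limma (Benjamini-Hochberg over the lists) and an adjusted p = 0.602 with an estimated correlation.

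**Figure D1:**
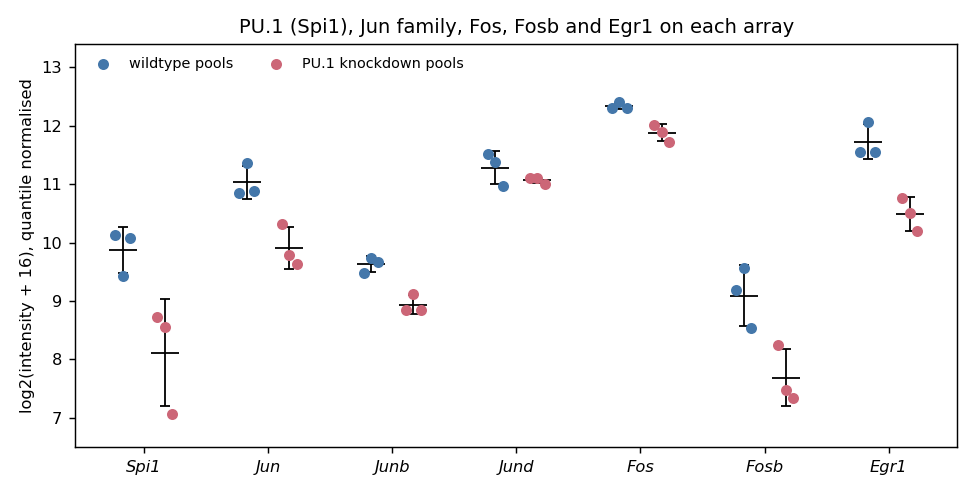
Log2(intensity + 16) after quantile normalisation for Spi1, Jun (1417409_at), Junb, Jund (1449117_at), Fos, Fosb and Egr1, 1 point per array, with mean and SD as bars, in 3 wildtype and 3 PU.1 knockdown pools. The knockdown points of Spi1 lie between 7.06 and 8.73 and the wildtype points between 9.42 and 10.13, while the groups overlap for Jund, whose other probe set changed sign with the values as deposited.

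Immediate early genes outside AP-1, which are induced within minutes of stimulation, were mostly lower in the knockdown pools, in 15 of 21 cases. Adjusted over the list alone, 7 passed the threshold, 6 of them lower. Egr1, a zinc finger transcription factor, averaged 11.72 ± 0.30 in wildtype and 10.49 ± 0.29 in knockdown pools (difference -1.23, SE 0.21). Klf2 differed by -1.66 (SE 0.38), Zfp36 by -1.18 (SE 0.29), Btg2 by -0.96 (SE 0.31), Dusp1 by -0.91 (SE 0.22) and Ier5 by -0.71 (SE 0.19). Myc, the growth-promoting transcription factor, went the other way, with 10.31 ± 0.07 in wildtype and 10.77 ± 0.16 in knockdown pools (difference 0.46, SE 0.14). Dusp6 differed by 0.20 (SE 0.16). The list had a mean difference of -0.38 and a camera adjusted p of 0.000174, against an adjusted p = 0.602 with an estimated correlation. Of the 21 genes, 0 passed over all probe sets.

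The naming rule kept probe sets with 1 gene symbol, groups that did not overlap and a mean above the median of all probe sets. Among these, the gene of smallest p with higher values in the knockdown pools was Sulf2, an extracellular sulfatase gene. It averaged 4.64 ± 0.96 in wildtype and 9.97 ± 0.73 in knockdown pools on 1447602_x_at (difference 5.32, SE 0.51), with 2 of the wildtype arrays at the floor, and its 3 probe sets differed by 0.027 to 5.32. Hpse, which encodes heparanase, averaged 7.17 ± 0.05 and 8.58 ± 0.19 (difference 1.42, SE 0.15). The other 8 higher genes under the rule were Lypd6b (3.20, SE 0.45), the myeloid lectin receptor gene Clec4e (2.59, SE 0.37), Isoc1 (2.03, SE 0.30), the actin-severing protein gene Scin (1.61, SE 0.26), the transcription factor gene Maf (1.59, SE 0.18), the kinase gene Dyrk3 (1.06, SE 0.14), Tedc1 (1.02, SE 0.16) and Slco3a1 (0.92, SE 0.15). For Maf, 5 of 6 probe sets had this sign, and for Isoc1, 3 of 4.

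Lower in the knockdown pools by the same rule was Slc35d3, a gene needed for platelet dense granules, with 9.0 ± 0.32 in wildtype and 6.66 ± 0.31 in knockdown pools (difference -2.34, SE 0.22). Ldhb, a lactate dehydrogenase subunit gene, differed by -1.62 (SE 0.20), the matrix protein gene Tgfbi by -1.56 (SE 0.23), and Gcsam by -1.37 (SE 0.17). Klf4, a transcription factor of monocytes, differed by -1.26 (SE 0.21) and Grk3, a G protein-coupled receptor kinase gene, by -1.22 (SE 0.15). Gucy1a1, a subunit of soluble guanylate cyclase, differed by -1.15 (SE 0.14). Differences of Snx24, Myom1 and Med12l were -1.07 (SE 0.15), -1.04 (SE 0.16) and -0.85 (SE 0.14). Over the probe sets of a gene the differences ran from -1.26 to -0.60 for Klf4, -1.22 to -0.30 for Grk3, -1.15 to -0.26 for Gucy1a1, -1.71 to -0.57 for Tgfbi and -0.85 to -0.26 for Med12l. These 20 genes had the smallest p in each direction under the rule and did not pass the threshold; dimmer probe sets with a smaller p, such as that of Thbs4 (adjusted p 0.202, 3 arrays at the floor), fell outside it.

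**Figure D2:**
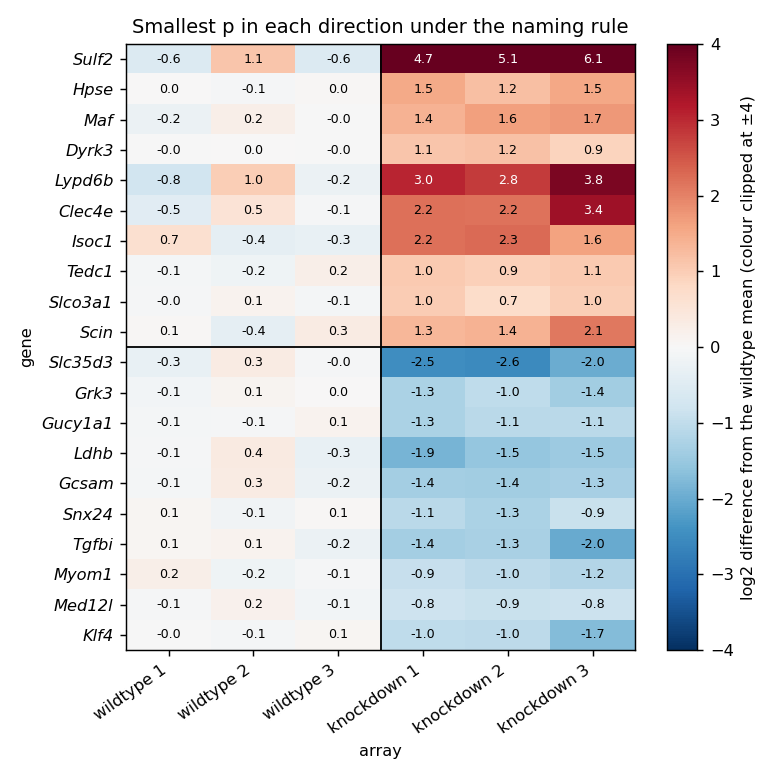
Log2 difference of each array from the wildtype mean for the 10 genes of smallest p in each direction under the naming rule, with colour clipped at a difference of 4 and the value printed in each cell. Mean differences run from 0.92 for Slco3a1 to 5.32 for Sulf2 in the upper block and from -2.34 for Slc35d3 to -0.85 for Med12l in the lower block.

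Of 44991 probe sets, 0 passed the limma test at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.171. At an unadjusted p under 0.05 there were 3200 probe sets, 1700 higher and 1500 lower, where 2250 are expected by chance, but a split of the arrays that mixed the genotypes gave 3676. The share higher among them was 53.1%, but 34.4% with the values as deposited, whose median difference was -0.048 in place of 0.009. At an unadjusted p under 0.001 there were 97 probe sets, 54 higher and 43 lower, beside 45 expected, and the ordinary linear model gave 67. The share higher among these was 55.7%, but 41.2% with the values as deposited. The groups did not overlap for 5782 probe sets, or 12.9%, where chance gives 10% for 3 against 3. Without wildtype pool 1, 2 or 3 the test called 1, 2 and 1 probe sets, and without knockdown pool 2 it called 1.

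Megakaryocyte and platelet genes were lower in the knockdown pools in 14 of 14 cases, with a mean difference of -1.19. Adjusted over the list alone, 2 passed, Selp, the P-selectin gene (-1.73, SE 0.47), and Gp9, a platelet glycoprotein gene (-1.32, SE 0.33), and 0 passed over all probe sets. Further members were Ppbp (-2.59, SE 1.13), Vwf (-1.68, SE 0.62) and Pf4 (-1.12, SE 0.54). Knockdown pool 2 was lowest for each of these, at 5.30 beside 9.95 and 9.87 for Ppbp, and without it Ppbp differed by -1.05 and Pf4 by -0.46. The camera adjusted p was 8.34e-08, against an adjusted p = 0.602 with an estimated correlation. List means were 9.87, 8.57 and 9.74 in wildtype pools 1, 2 and 3 and 8.80, 7.18 and 8.65 in knockdown pools 1, 2 and 3, so wildtype pool 2 lay below knockdown pools 1 and 3. Without knockdown pool 2, the mean difference was -0.67 and the camera adjusted p 0.000129.

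Myeloid receptor and phagocyte genes, many of them known PU.1 targets, were lower in 22 of 27 cases, with a mean difference of -0.42. Csf2ra, a subunit of the GM-CSF receptor, averaged 9.78 ± 0.42 in wildtype and 8.77 ± 0.13 in knockdown pools (difference -1.0, SE 0.22). Its 2 probe sets differed by -1.0 and -0.13. The lipopolysaccharide co-receptor gene Cd14 differed by -0.96 (SE 0.29) and Ctss, a lysosomal protease gene, by -1.27 (SE 0.39). Irf8, a transcription factor gene of the myeloid lineage, had a log2 value of 7.26 in knockdown pool 3 and 9.92 to 10.53 in the other 5 pools. Fcer1g and Ncf4 had differences of 0.28 (SE 0.25) and 0.15 (SE 0.35), and Ncf4 changed sign with array weights (-0.097). Adjusted over the list alone, 0 of the 27 passed. The camera adjusted p was 1.27e-05, against an adjusted p = 0.602 with an estimated correlation. The mean difference was -0.21 without wildtype pool 1 and -0.67 without wildtype pool 2, which had a list mean of 8.56 beside 9.41 and 9.20. Wildtype pool 2 thus lay below knockdown pools 1 and 2, at 8.92 and 8.76, so the groups overlapped. Knockdown pool 3 had the lowest list mean of all arrays.

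Stem cell genes were lower in 20 of 29 cases, with a mean difference of -0.20. Tek, the angiopoietin receptor gene, differed by -0.99 (SE 0.21) and was the 1 member past the threshold adjusted over the list alone. Prdm16, a transcriptional regulator of HSC maintenance, differed by -1.31 (SE 0.33), while Fgd5 and Myct1 had differences of 0.43 (SE 0.23) and 0.27 (SE 0.25). The camera adjusted p was 0.0164, against an adjusted p = 0.858 with an estimated correlation. Wildtype pool 2 had the highest list mean, 9.79 beside 9.19 and 9.13, and without it the mean difference was 0.056 with a camera adjusted p of 0.591. The call was also lost with array weights and without knockdown pool 1.

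MHC class II and dendritic cell genes were lower in 8 of 10 cases, with a mean difference of -0.38. Cst3 and Cd83 differed by -0.60 (SE 0.18) and -0.60 (SE 0.27), and H2-DMa by 0.28 (SE 0.24), with Ciita at 0.0076 (SE 0.15). The camera adjusted p was 0.0164, against an adjusted p = 0.602 with an estimated correlation. Knockdown pool 3 had a list mean of 8.02 beside 8.69 and 8.86, and without it the mean difference was -0.13 and the adjusted p 0.304; the call was also lost without wildtype pool 2. B lymphoid genes were lower in 13 of 19 cases, with a mean difference of -0.29 that did not pass (camera adjusted p 0.0532). Without 1 array the mean difference ranged from -0.485 to -0.0039 (adjusted p 0.00169 to 0.869), and the value nearest 0 was that without knockdown pool 3. Adjusted over the list alone, 5 passed, with Fcrla (-1.40, SE 0.40), the adaptor gene Blnk (-1.10, SE 0.27), Cd79b (-1.06, SE 0.31) and Ms4a1 (-0.86, SE 0.24) lower and Cd72 higher (1.14, SE 0.33). Igll1 differed by 0.24 (SE 0.16). Knockdown pool 3 again lay lowest, with a B lymphoid mean of 7.39 beside 8.35 and 8.14.

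T and NK genes were higher in the knockdown pools in 15 of 18 cases, with a mean difference of 0.31 and a median of 0.16. Gzmb had the largest difference, and 5 of the 18 had a wildtype mean above the median of all genes. Adjusted over the list alone, 2 passed, Gzmb, a granule protease gene also known from mast cells (5.90 ± 0.92 in wildtype and 8.59 ± 0.85 in knockdown pools, difference 2.69, SE 0.53), and Bcl11b, a T lineage transcription factor gene (0.80, SE 0.16). Gzma and Cd28 had differences of -0.54 (SE 0.28) and -0.48 (SE 0.33). The camera adjusted p was 0.0307, against an adjusted p = 0.602 with an estimated correlation. The call was lost without wildtype pool 2 or knockdown pool 3, with both filters on dim probe sets (adjusted p 0.41 above the 60th percentile) and with array weights.

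DNA replication genes were higher in 18 of 23 cases by a small margin, with a mean difference of 0.12 and a camera adjusted p of 0.0295, against an adjusted p = 0.602 with an estimated correlation. Tk1 differed by 0.42 (SE 0.17) and the primase gene Prim1 by 0.39 (SE 0.14), while Tyms and Rrm2 had differences of -0.19 (SE 0.17) and -0.10 (SE 0.24), a sign shown by 1 of 4 Tyms and 1 of 3 Rrm2 probe sets. The call was lost without wildtype pool 1 or 2 and without knockdown pool 2 (adjusted p 0.216) or 3. Mitosis genes had 15 of 20 members higher with a mean difference of 0.10 and did not pass (camera adjusted p 0.212). Wildtype pool 2 had a mitosis mean of 9.99 beside 10.47 and 10.58, and the difference was -0.074 without it and 0.22 without wildtype pool 3 (adjusted p 0.00627). Kif11 and Tpx2 differed by 0.36 (SE 0.18) and 0.33 (SE 0.23), and Nusap1 and Cks2 by -0.15 (SE 0.18) and -0.10 (SE 0.18).

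Mast cell, basophil and eosinophil genes went in both directions, with 7 of 10 higher. Carboxypeptidase gene Cpa3 (2.05, SE 0.35) and the basophil protease gene Mcpt8 (1.71, SE 0.46) were higher in the knockdown pools. The eosinophil granule genes Epx (-3.69, SE 0.88) and Prg2 (-3.06, SE 0.74) were lower. These were the 4 members past the threshold adjusted over the list alone. The mean difference of -0.010 and the median of 0.41 had opposite signs, and the camera adjusted p was 0.277 in the upward direction; without wildtype pool 1 the mean was 0.342 with an adjusted p of 0.02. Neutrophil and granule genes, at a high mean of 10.96 in both groups, had a mean difference of 0.0022 (camera adjusted p 0.753). Ngp and Camp, of secondary granules, each had a difference of 1.08 (SE 0.37 and 0.41), and Chil3 and Mmp9 had differences of -3.41 (SE 1.02, 1 knockdown array at the floor) and -0.88 (SE 0.56). Wildtype pool 2 had a neutrophil list mean of 9.91 beside 11.65 and 11.33, and without it the mean difference was -0.52 with a camera adjusted p of 0.0288, while without wildtype pool 1 it was 0.345 with an adjusted p of 0.0169.

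**Figure D3:**
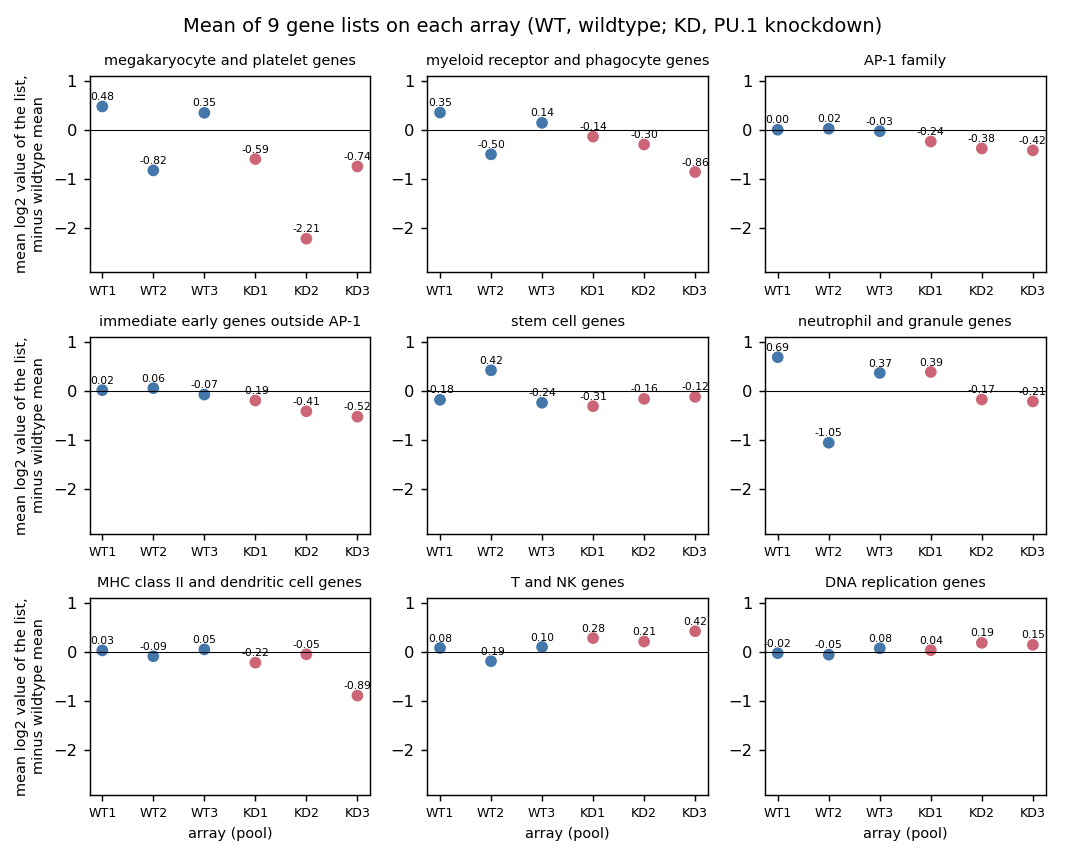
Mean log2 value of the members of 9 gene lists on each array, minus the mean of the wildtype arrays, with wildtype pools in blue and PU.1 knockdown pools in red on a common axis. Wildtype pool 2 stands apart for megakaryocyte, neutrophil and stem cell genes, with list means of 8.57, 9.91 and 9.79, knockdown pool 2 for megakaryocyte genes, with 7.18, and knockdown pool 3 for MHC class II genes, with 8.02.

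The remaining lists did not pass with all arrays and the settings fixed beforehand. Calls gained in alternatives were 4 of 18 for interferon, 6 of 18 for respiratory chain, and 1 of 18 each for ETS, stromal and ribosomal genes. ETS family genes other than Spi1 were lower in 12 of 16 cases (mean difference -0.096, camera adjusted p 0.212), with Elk3 at -0.53 (SE 0.19) and Ets1 at -0.33 (SE 0.19) and, higher, Etv5 at 0.55 (SE 0.20) and Etv6 at 0.12 (SE 0.21). Interferon response genes were higher in 13 of 17 cases (0.26, adjusted p 0.111), with Bst2 at 1.04 (SE 0.38) and Ifit3 at 0.40 (SE 0.17) and, lower, Oas1a at -0.79 (SE 0.58) and Oas2 at -0.29 (SE 0.23). Knockdown pool 2 had the highest interferon mean, 9.04 beside 8.44 and 8.03, and without it the list difference was -0.0085. Oas1a was 7.47 in knockdown pool 3 beside 9.54 and 9.82, and with 1 array left out the value nearest 0 was -0.056 for Oas1a and -0.067 for Oas2. Erythroid genes were higher in 10 of 16 cases (0.11, adjusted p 0.764), with Car2 and Nfe2 at 0.24 (SE 0.14 and 0.19) and Tfrc and Hba-a1 at -0.34 (SE 0.27) and -0.18 (SE 0.19). The erythroid mean was highest in knockdown pool 2, and the difference was -0.232 without it and -0.164 without wildtype pool 2. Stromal and endothelial genes had 9 of 16 higher, and 2 passed adjusted over the list alone, Pdgfrb, higher (2.00, SE 0.37), and Kdr, lower (-0.99, SE 0.23). Bgn and Col3a1 differed by -0.61 (SE 0.22) and 0.17 (SE 0.18), and the stromal mean of 0.063 and median of 0.041 stood against a downward camera test (adjusted p 0.281), with -0.223 without wildtype pool 2 (adjusted p 0.0288).

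Among p53 targets and cell cycle inhibitors, 7 of 16 were higher, and Phlda3 (0.82, SE 0.15) was the 1 member past the threshold adjusted over the list alone. Cdkn2b differed by 0.24 (SE 0.13), Pmaip1 by -0.47 (SE 0.24) and Cdkn2c by -0.43 (SE 0.24), and the list mean of 0.043 and median of -0.011 differed in sign (camera adjusted p 0.822, upward). Heat shock genes had 7 of 11 higher with a median of 0.057 but a mean of -0.20 (adjusted p 0.893, downward). Hspa1a (-2.02, SE 0.66) and Hspa1b (-1.06, SE 0.55) stood against Hsph1 (0.52, SE 0.27) and Hspe1 (0.21, SE 0.22). Knockdown pool 2 did not share the lower values, at 9.18 beside 6.78 and 6.67 for Hspa1a and 11.84 beside 9.74 and 9.79 for Hspa1b. For both genes it lay above wildtype pool 2 (8.85 and 11.01). In the BCL2 family, 5 of 10 were higher (mean 0.0059, median -0.027, camera adjusted p 0.961, downward). Bmf differed by 0.43 (SE 0.15), Bcl2l11 by 0.36 (SE 0.20), Bik by -0.44 (SE 0.20) and Mcl1 by -0.30 (SE 0.16). Wnt and Notch genes were higher in 9 of 15 cases (mean 0.0099, adjusted p 0.961), with Hes1 at 0.38 (SE 0.17), Jag1 at 0.30 (SE 0.16), Lef1 at -0.45 (SE 0.28) and Fzd7 at -0.28 (SE 0.16). Ribosomal protein genes were higher in 23 of 45 cases (mean 0.029, adjusted p 0.961), with Rps16 at 0.83 (SE 0.21, 2 arrays at the floor), Rpl39l at 0.38 (SE 0.22), Rpl22l1 at -0.27 (SE 0.15) and Rpl27a at -0.15 (SE 0.17). Genes of the respiratory chain were higher in 63 of 98 cases (mean 0.064, adjusted p 0.0981), with Cox8c at 0.44 (SE 0.17), Ndufaf7 at 0.35 (SE 0.13), Cox16 at -0.37 (SE 0.18) and Cox7c at -0.30 (SE 0.25). With 1 array left out the list means of p53, Wnt and Notch and BCL2 genes took either sign, and that of heat shock genes ran from -0.43 to -0.0525.

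Probe sets of opposite sign were also found for Ier5, Etv5, Etv6, Ets1, Prdm16, Igll1, Bcl11b, Tfrc, Tpx2, Nusap1, Cks2, Bcl2l11, Bik, Cox8c and Cox16. Leaving out 1 array moved 54 of the 125 named probe sets besides PU.1 and Thbs4 by over 1.5 times. Of these, 9 had a difference above 2-fold with all arrays, Ppbp and Pf4 as given, Chil3 (-4.24 to -2.27), Fcrla (-1.76 to -0.93), Ctss (-1.63 to -0.82), Hspa1b (-1.76 to -0.69), Ngp (0.69 to 1.52), Camp (0.57 to 1.45) and Bst2 (0.69 to 1.53). Of the 22 lists, 8 passed the preset camera test, 6 lower and 2 higher in the knockdown pools. Adjusted over the list alone, 0 members passed in the MHC class II, DNA replication, mitosis, neutrophil, ETS, interferon, erythroid, heat shock, BCL2, Wnt and Notch, ribosomal and respiratory chain lists, and over all probe sets 0 members of any list passed. With an estimated correlation 0 lists passed, and fry, which asks whether a list's genes move one way on balance, gave 0 with a smallest adjusted p of 0.13. Its mixed test, which asks for change in either direction, had adjusted p values of 0.0139 for AP-1, 0.0423 for the other immediate early genes and 0.0423 for p53 targets.

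**Figure D4:**
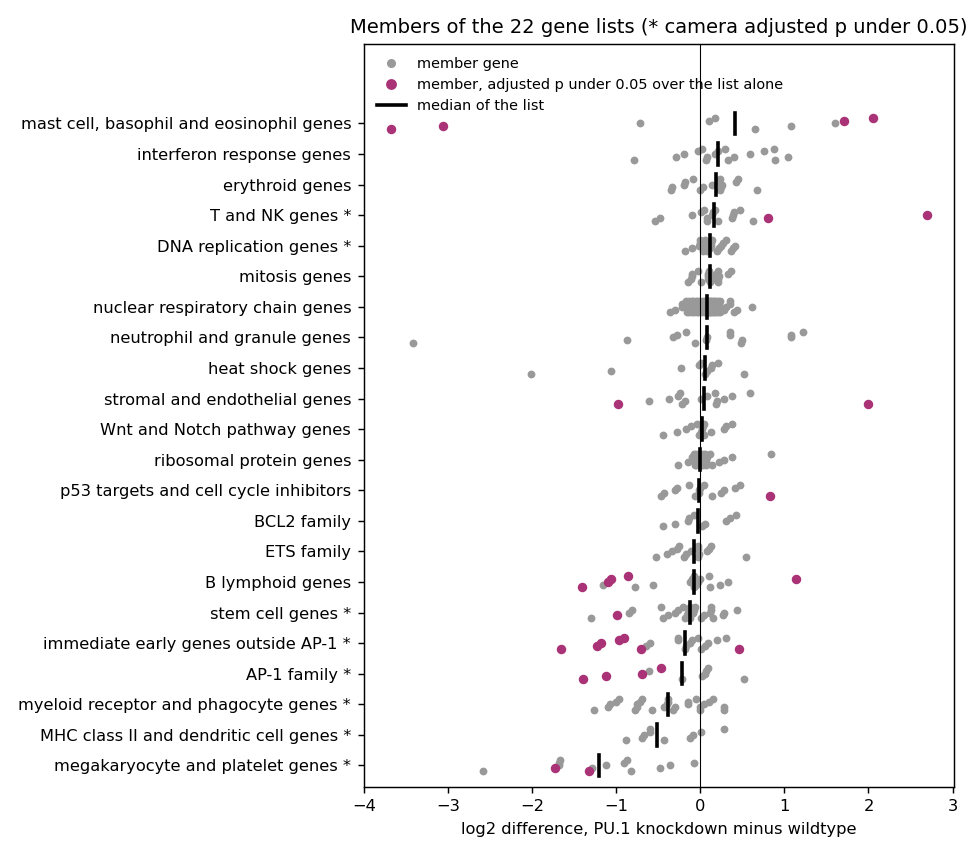
Log2 difference, knockdown minus wildtype, of each member (points) of the 22 gene lists (rows, ordered by median), with the median as a bar, members past the threshold adjusted over the list alone in purple, and a star for a camera adjusted p under 0.05 at the preset correlation. All 14 megakaryocyte and platelet genes lie below 0, and mast cell, basophil and eosinophil genes spread from -3.69 for Epx to 2.05 for Cpa3.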

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

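The alternatives were planned before the data were examined, and results not listed kept their sign in each alternative run; the causes of the shifts below were not tested unless stated. Of 120 named probe sets besides PU.1, the Jun genes and Thbs4, 114 kept their sign in every alternative and 6 did not. Among the 120, Sulf2 alone passed the threshold in one (without wildtype pool 2, limma adjusted p 0.0432, range 0.0432 to 0.593 over arrays left out). Spi1 stayed lower throughout, at -2.08 to -1.24 with 1 array left out. The count of probe sets past the threshold was 0 in each full-array alternative and ranged from 0 to 1 higher and from 0 to 1 lower with 1 array left out. Those called, seen only then, were Pdxdc1 (4.33, without wildtype pool 1), Npy (-2.58) and Sulf2 (5.86, both without wildtype pool 2), Ighm (-5.34, without wildtype pool 3) and Thbs4 (4.97, without knockdown pool 2, 3 arrays at the floor). The number of gene lists past the threshold went from 8 to 0 under both the estimated correlation and fry. It ranged from 6 to 11 with 1 array left out. The estimated correlation replaces 0.01 by the members' own. For AP-1 genes the mean within-group correlation was -0.018, below 0.01, so this replacement alone does not account for the loss of that list. The AP-1, immediate early, myeloid and megakaryocyte calls were kept in all 16 alternatives with the preset camera test, and B lymphoid genes passed in 8 of all 18. Lists called only in an alternative were interferon (adjusted p 0.0202 with array weights, 0.017 with the replicate block, 0.00305 without wildtype pool 2, 0.0016 without knockdown pool 3), respiratory chain (6 alternatives, 0.00161 to 0.0473), ribosomal (0.0361, centred on medians), mitosis (0.00627, without wildtype pool 3), ETS (0.0312) and mast cell, basophil and eosinophil genes (0.02, both without wildtype pool 1), stromal (0.0288, without wildtype pool 2) and neutrophil genes (0.0169 upward without wildtype pool 1, 0.0288 downward without wildtype pool 2). At an unadjusted p under 0.001, 97 probe sets became 157 with array weights and 40 above the 60th percentile. That count was 182 without wildtype pool 2, 56 without wildtype pool 1 and 61 without knockdown pool 3. At p under 0.05, 3200 became 2094 and 1475 above the 40th and 60th percentiles, where fewer were tested. The share higher at p under 0.05 was 63.1% in the ordinary model. At p under 0.001 the share was 70.1% there, 44.1% with the replicate block and 35.3% without wildtype pool 3. With the values as deposited, differences turned for Jund 1440265_at (-0.026), Ciita (-0.048) and the lists of neutrophil (-0.017), p53 (-0.021), Wnt and Notch (-0.052) and BCL2 genes (-0.0625). Array weights turned Ncf4 (-0.097). A pseudocount of 1 turned the neutrophil (-0.059) and mast cell, basophil and eosinophil lists (0.061). The 60th percentile filter turned the neutrophil (-0.022) and p53 lists (-0.0595). With 1 array left out, differences ranged from -0.034 to 0.14 for Jund 1440265_at, -0.021 to 0.30 for Etv6, -0.25 to 0.38 for Ncf4, -0.059 to 0.099 for Ciita, -0.34 to 0.041 for Rrm2, -0.21 to 0.034 for Cks2 and -1.35 to 0.28 for Irf8. List means ranged from -0.52 to 0.35 for neutrophil, -0.27 to 0.056 for stem cell, -0.23 to 0.32 for erythroid, -0.45 to 0.34 for mast cell, basophil and eosinophil, -0.22 to 0.31 for stromal, -0.074 to 0.22 for mitosis, -0.013 to 0.088 for p53, -0.0085 to 0.50 for interferon, -0.021 to 0.054 for Wnt and Notch, and -0.042 to 0.068 for BCL2 genes. Both groups carry numbers 1 to 3, but pools of equal number deviated from their group means with correlations of 0.18, 0.061 and -0.039, and the labels give no shared origin. With the replicate number as a block 0 probe sets passed (smallest adjusted p 0.0629), and 3314 had an unadjusted p under 0.05. Filters removed some dim probe sets, which then have no value. What limits the data is 3 arrays per group, variation between pools of one genotype and, for dim probe sets, signal near the floor.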

Other observations

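The tests of array scaling, of shared variation among megakaryocyte and among AP-1 and immediate early genes, and of a mixed granulocyte population were chosen after the results they bear on had been seen. The split of the mixed granulocyte list into separate eosinophil and mast cell lists was likewise made after seeing the data.

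Eosinophil and mast cell genes are described here as values, since their lists were written after the data were seen. They were not tested with camera or fry, and 0 members passed over all probe sets. The eosinophil list was written with 12 genes, of which 8 were matched to a probe set. Of these 8, 7 had lower means in the knockdown pools, among them Ccr3, near the floor at 4.09 to 5.07. The list mean of the 8 genes was 9.04, 7.13 and 8.14 in wildtype pools 1, 2 and 3 and 6.55, 5.78 and 5.28 in knockdown pools 1, 2 and 3. Wildtype pool 2 thus lay nearest the knockdown pools. Prg3 differed by -3.68 (SE 0.87), the ribonuclease gene Ear3 by -3.41 (SE 0.63) and Alox15 by -2.27 (SE 0.48, 1 knockdown array at the floor), the last 2 with deposited knockdown intensities near background, beside the Epx and Prg2 values already given. The interleukin-5 receptor gene Il5ra, which marks eosinophil precursors, had a difference of 0.0018 (SE 0.25). Of 15 mast cell and basophil genes, 12 had higher means in the knockdown pools, with list means of 6.75 ± 0.31 and 7.37 ± 0.40. Cma1, the chymase gene, was 5.82, 6.94 and 8.76 in knockdown pools 1, 2 and 3 and 5.51 to 5.65 in wildtype pools, and the tryptase gene Tpsb2 was 8.0 in knockdown pool 3 and at most 6.69 in the others. Mitf, a mast cell transcription factor gene, went the other way (-0.70, SE 0.21). Of these eosinophil genes 2, and of the mast cell genes 9, are also in the lists fixed beforehand, among them Gzmb of the T and NK list. Over the alternatives the eosinophil mean difference ran from -3.48 to -1.70 and the mast cell one from 0.36 to 0.79.

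The mast cell minus eosinophil difference between the groups was 2.86 (SE 0.70), but the lists were parted because of this contrast, so it decides nothing about 1 mixed population. A smaller share of eosinophil-lineage cells in the knockdown pools is a possible explanation that was not settled. The 8 genes varied together between pools of one genotype (mean correlation 0.447, against a 95th percentile of 0.205 among 1000 random lists matched on expression), but so did 15 of the 22 lists, among them mitosis (0.668), heat shock (0.642), interferon (0.475) and neutrophil genes (0.713). How far the sort removed mature eosinophils is not known, as its markers are not given in the sources used here. Neutrophil and granule genes averaged 10.96 in both groups, so transcripts of granule genes were present in the pools. Control of these genes by PU.1 within the sorted cells remains open and untested.

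For the megakaryocyte and platelet genes, the mean difference was -1.25 with the values as deposited, so the quantile normalisation did not create it. The camera adjusted p there was 8.06e-07, with a range of 4.91e-19 to 0.000129 over the alternatives with the preset correlation. With an estimated correlation the camera adjusted p was 0.602. Array scaling is not excluded, as the deposited values carry an unknown scaling. Their median difference over all probe sets was also lower, -0.048 in place of 0.009, so a lower list could hardly shrink. The 14 genes varied together between pools of one genotype, with a mean correlation of 0.848 against a 95th percentile of 0.108 among random lists. An unequal share of megakaryocyte-lineage cells or platelets may give this, but lists that mark no cell type were coherent too, so the test does not settle it. How far the sort removed platelets and mature megakaryocytes is not known, as its markers are not given in the sources used here. A platelet-biased HSC state and the PU.1 level itself remain open and untested.

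For the 32 AP-1 and immediate early genes, the mean difference was -0.423 as deposited, so the quantile normalisation did not create it. Array scaling is likewise not excluded, for the same reasons. Both lists passed the camera threshold as deposited (higher adjusted p 0.0119). The range over both lists was 4.93e-06 to 0.0316 in the alternatives with the preset correlation, but the adjusted p was 0.602 for each with an estimated correlation. Unequal activation of cells during sorting is a possible explanation that was not settled: the members varied together between pools of one genotype (mean correlation 0.106, 95th percentile of random lists 0.0484), as most lists did. Among themselves the immediate early genes outside AP-1 gave 0.138, and AP-1 genes gave -0.018, near their random median of -0.016. The value of 0.106 also averages pairs across the lists, whose correlation was not computed apart. Whether the 32 genes follow the megakaryocyte genes cannot be told apart, with a correlation of the 2 means within groups of 0.074 over 6 arrays. The PU.1 level itself remains open and untested.

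The 6 arrays make 10 splits into 3 against 3, too few for a share under 0.05. With a real count of 0 probe sets past the threshold, 10 of 10 splits must give at least as many, so that count decides nothing, and the highest other count was 1. The 97 probe sets at an unadjusted p under 0.001 were matched in 1 of 10 splits, the real one, and the highest other count was 63. At an unadjusted p under 0.05, however, the real 3200 was reached in 2 of 10 splits, as wildtype pools 1 and 3 with knockdown pool 1 against the rest gave 3676. At least 8 gene lists passed in 7 of 10 splits, and the highest other count was 13.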
